A study of Mus musculus with 6 samples.

How the data were processed

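Messenger RNA was sequenced from germinal centre B cells of mouse spleen, isolated by bead enrichment of B cells and then cell sorting, in 3 KO and 3 WT libraries. Per the labels' protocols, libraries were made with an Illumina TruSeq mRNA kit and sequenced on a NextSeq500 in paired-end mode with 150 cycles. Per the submitters' processing notes, the tools were FastQC 0.11.7, Trim Galore 0.6.5, STAR 2.6.1a, featureCounts, Subread 2.0.1 and limma, and the genome build was mm10. The notes used here give no settings or order for them, and the strand setting of the counting is not given in the sources used here.

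The deposited values are on a log2 scale, 1 value per gene and library for 23420 genes, rounded to 3 decimals. Their meaning was worked out from the values themselves. Linear values summed to between 997617 and 1000513 per library, as log2 CPM do. The most common value was -5.063, called the floor here, and 8492 genes held it in all 6 libraries. Single values of other genes lay below the floor, for example -6.842 for Ngp in KO 1. Among genes near the floor the most common nonzero difference within a pair was 1.58 in size. An offset of 0.5 reads predicts log2(3) = 1.585 between 0 and 1 read. Under that offset the floor would correspond to a geometric mean depth of 16.7 M reads, but the depth of the single libraries is unknown. All 6 libraries had the same highest value of 13.94 and nearly the same distribution, as quantile normalization leaves it. Of the genes above the floor 26 had 1 value in all 6 libraries. Such a step can erase differences of top-ranked genes, and 6 of the 26 lay above 1 CPM, all at 12.15 log2 CPM or more (Cd74, H2-Ab1, Pfn1, Tmsb4x, Cfl1 and Eef1a1).

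The deposited log2 values also lacked any difference between replicate numbers: the sum of WT and KO values with the same number was equal over the 3 numbers for every gene, to within 0.001. This is what removal of a replicate effect leaves. It has 3 consequences. WT and KO libraries have equal SDs by construction; the correlation between libraries of the same number is fixed, so it cannot show whether the numbers pair the samples; and 2 degrees of freedom per gene are already used. The labels do not say what a replicate number stands for. A fit without a replicate block would count those 2 degrees of freedom as if they were still free. Data were simulated with the same removal (10133 genes, 200 of them drawn at random and changed, 10 runs). The cytosolic ribosomal protein list was also raised by 0.2 on the log2 scale, and calls of its members did not count as false. The fit without the block had 50.4% false calls among its calls at 5% FDR and the fit with it 4.93%, so the replicate number was kept as a block.

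The planned test had assumed read counts and no block. Since the files hold log2 values, KO was compared with WT by limma 3.58.1 in R 4.3.3 (linear model with genotype and replicate number, empirical Bayes moderation with a variance trend over expression level and robust estimation, two-sided), with Benjamini-Hochberg adjustment at 5% FDR. Genes with a mean of at least 1 CPM over the 6 libraries were tested, and genes with 1 value in all libraries were left out, which gave 10133 genes. Robust estimation was planned before the data were examined. The variance trend, the limit on the mean and the treatment of genes with equal values were fixed after several fits had been seen, and the closing section gives the counts without each of them. The model has 2 residual degrees of freedom per gene and a median of 81.2 prior ones, so most of the information on a gene's spread came from other genes. An exact sign-flip test of 3 pairs cannot give a two-sided p below 0.25 for 1 gene alone. In the simulation the fit with the block recovered 70.7% of genes changed by 0.5 on the log2 scale, 92.8% of those changed by 1 and 99.9% of those changed by 2, and 4.91% of unchanged genes had an unadjusted p under 0.05. The simulated genes were independent and all had 81.2 prior degrees of freedom, which in the libraries went down to 0.299. The rates in the libraries may therefore be worse.

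Fold changes are differences of deposited log2 CPM, KO minus WT, with the SD over the 3 replicate numbers, and CPM given for a group are geometric means. The offset shrinks the fold changes of genes near the floor. Genes were named by a rule fixed before the data were examined. It takes Basp1, then the 12 genes that rose and the 12 that fell with the largest fold change past 5% FDR, with all KO libraries beyond all WT libraries and a mean of at least 2 CPM, then up to 4 members per list with the smallest p, then 15 textbook genes. Some genes that this rule names are not reported here. With the equal pair sums, separation of the groups follows whenever all 3 pairs go one way, which chance gives in 25% of genes.

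Gene lists were 32, fixed before the data were examined, for B cell states, signalling, metabolism, other cell types and RNA quality. The 24 with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera with an estimated correlation rests on the 2 residual degrees of freedom alone, so it has little power here. The lists of immunoglobulin constant regions and mitochondrially encoded transcripts had no members among the genes used here, and the other 6 untested lists were markers of other cell types, given as summed CPM. Coordinates, transcript length and GC content came from an annotation of GRCm38, to which 21571 symbols matched directly and 1688 through a synonym, while 161 did not match. Length and GC content were known for 10072 of the 10133 tested genes (99.4%). In list comparisons, 10000 random lists were drawn from the 30 genes nearest to each member in length, GC content and mean level.

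Alternatives were other filters on low values, 1 CPM added before the log, no block, non-robust moderation, no variance trend, genes with equal values kept, a test of a fold over 1.2, removal of the length and GC trend and leaving out each replicate number. Since the pair sums are equal, leaving out 1 library takes its partner with it. Settings that need read counts, fixed before the data were examined, were not run.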

Results

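The data were messenger RNA profiles of germinal centre B cells, the antigen-activated B cells that mutate their antibody genes and are selected for affinity inside lymphoid follicles. The cells came from spleens of mice on day 10 after immunization with NP-KLH, a hapten coupled to a carrier protein. Both groups carried hCD20TamCre, a Cre recombinase of B cells that tamoxifen activates, and tamoxifen (1 mg) was given to both on day 5, day 7 and day 9. In the KO group both Basp1 alleles were floxed, and in the WT group both were intact. Basp1 encodes a myristoylated protein of the inner plasma membrane that binds calmodulin and phosphoinositides and that also acts as a transcriptional co-repressor. Each group had 3 libraries, numbered 1 to 3. The labels do not state that the libraries came from separate mice, so the p-values rest only on spread between these libraries. For each gene most of that spread was estimated from other genes of like level, not from its own 3 pairs.

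Each library listed a log2 CPM value for the same 23420 genes. Between 10160 and 10173 genes per library lay at or above 1 CPM, and the listed values summed to between 997617 and 1000513 CPM. The read depth of each library is unknown, since the values were already scaled and put on a common distribution. The values also carried no difference between replicate numbers: for every gene, WT and KO values with the same number had the same sum to within 0.001. What remained per gene was therefore a mean and 3 paired differences, and each fold change below is the mean of those 3 differences with their SD (n = 3 pairs). Precision followed expression level. The median SD of the paired differences was 0.342 on the log2 scale for the 2213 genes between 1 and 8 CPM, 0.162 for the 4591 between 8 and 64 CPM, and 0.112 for the 3329 above 64 CPM.

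Basp1 itself was lower in all 3 KO libraries than in all 3 WT libraries. The WT mean was 5.64 log2 CPM (49.7 CPM) and the KO mean 3.12 (8.70 CPM), a log2 fold change of -2.51 ± 0.45 (SD, n = 3 pairs; limma adjusted p = 3.3e-16). The paired differences were -2.22, -3.03 and -2.29. KO libraries thus kept a fraction of 0.175 of the WT level. The gene lies on the minus strand of chromosome 15 from 25363277 to 25413764 (GRCm38, the build called mm10). Its main transcript has 2 exons, and the whole 678-bp coding sequence, from 25364232 to 25364909, lies in exon 2, while exon 1 (25413552 to 25413764) is untranslated. The labels do not say which part was floxed, so the values do not tell how much of the remaining signal came from undeleted alleles and how much from transcript outside the deleted part.

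The comparison of KO with WT asked which transcripts differed in germinal centre B cells of the group with floxed Basp1. How much BASP1 protein remained in them is not known from these data. Among called genes with a mean of at least 2 CPM, Tbx21 and Cxcr3 rose most. Tbx21, which encodes the transcription factor T-bet, rose from 4.48 to 13.5 CPM, a log2 fold change of 1.59 ± 0.41 (SD, n = 3 pairs; limma adjusted p = 1.2e-10; chromosome 11, 97098007 to 97115331). Cxcr3, a chemokine receptor gene that T-bet is known to activate, rose from 3.15 to 7.79 CPM, by 1.31 ± 0.20 (adjusted p = 1.8e-05; chromosome X, 101731535 to 101734147). In all, 27 of the 10133 genes tested passed 5% FDR, 17 higher and 10 lower in KO, and each of the 27 differed the same way in all 3 pairs. At an unadjusted p under 0.05 there were 894 genes (8.82%), 422 higher and 472 lower. That agreement follows largely from selection by a paired test. Among all tested genes 28.1% went one way in all 3 pairs, against 25% by chance. Over the 10133 genes the paired differences of pairs 1 and 2 had a Pearson correlation of 0.133, those of 1 and 3 of -0.0129, and those of 2 and 3 of 0.105. The count of 27 depended on replicate pair 2, without which 11 genes were called and 4 of the 27 were among them. The excess of rises was not stable: 27 genes were higher and 109 lower without pair 1, 4 and 7 without pair 2, and 28 and 71 without pair 3. It fell to 0 when the variance was not modelled along expression level, where 640 genes had an unadjusted p under 0.05 and Basp1 itself had an adjusted p of 0.150.

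**Figure D1:**
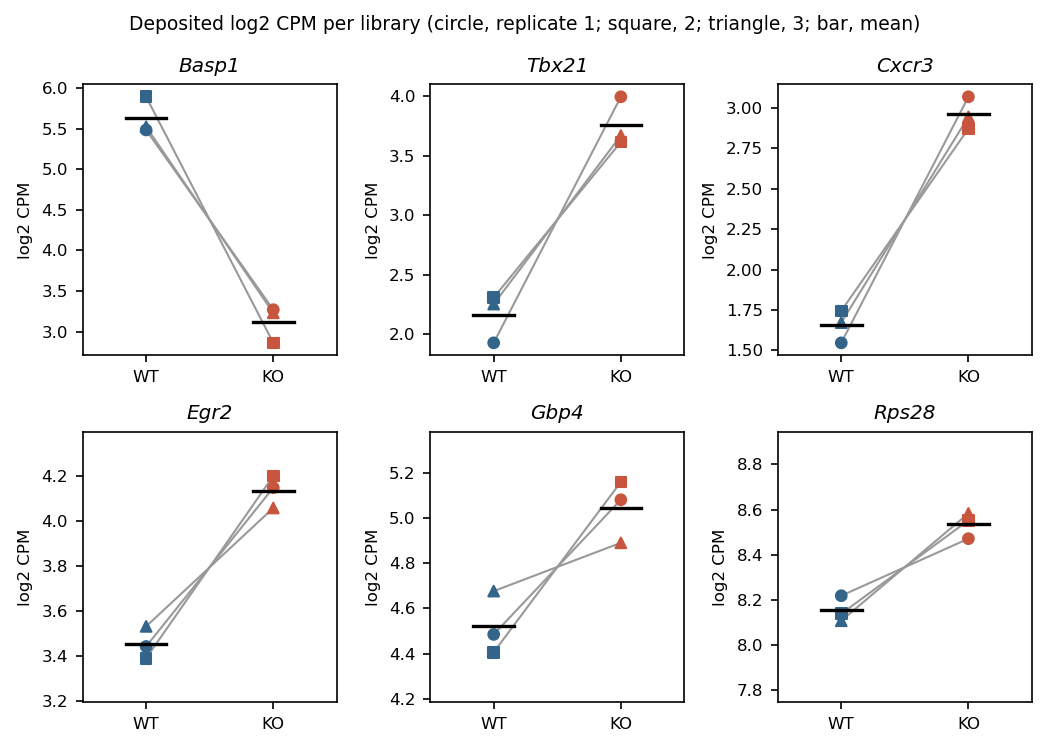
Deposited log2 CPM of Basp1, Tbx21, Cxcr3, Egr2, Gbp4 and Rps28 in each WT library (blue) and KO library (red), with the group mean as a bar and a grey line joining libraries of the same replicate number. In each panel all 3 KO points lie on one side of all 3 WT points, and the mirrored spread of the 2 groups follows from the equal pair sums; the vertical axes differ between panels and do not start at 0.

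Among the other transcripts that rose, Egr2, an early response gene of antigen receptor signalling, rose by 0.68 ± 0.14 (limma adjusted p = 0.00366), and Jun, a subunit of the AP-1 factor, by 0.90 ± 0.31 (adjusted p = 0.0482). Rasgrf2, a guanine nucleotide exchange factor for Ras that calcium and calmodulin regulate, rose by 1.25 ± 0.13, from 1.86 to 4.44 CPM (adjusted p = 0.00258). Gbp4 and Ifi47, both interferon-inducible GTPases, rose by 0.52 ± 0.28 (adjusted p = 0.00929) and 0.44 ± 0.34 (adjusted p = 0.0431). The serpin gene Serpina3g rose by 0.68 ± 0.37 (adjusted p = 0.0428). Rises of under 0.5 were found for the ribosomal protein genes Rps28 (0.38 ± 0.12) and Rps29 (0.33 ± 0.10), for Ogt, the enzyme that adds O-GlcNAc to proteins (0.38 ± 0.27), and for D4Wsu53e, now named Rsrp1 (0.40 ± 0.18). The other 5 genes that rose fell outside the rule for naming and are given because they complete the count: Tgtp2, Pydc3, Rpl41, Rpl37a and Rps26. Tgtp2 (1.26 ± 0.41) and Pydc3 (1.43 ± 1.05) lay near 1 CPM in WT. Apart from Tbx21 and Cxcr3, no gene that rose stayed past 5% FDR in the test of a fold over 1.2, with the trend over transcript length and GC content removed, or without pair 2.

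Beside Basp1, 9 transcripts fell. Anp32a, a nuclear phosphoprotein of the acidic leucine-rich family, changed by -0.67 ± 0.36 on the log2 scale (limma adjusted p = 0.00207), and Cdk13, a kinase of transcription elongation, changed by -0.65 ± 0.34 (adjusted p = 0.0367). Sepp1, now named Selenop, which encodes the selenium carrier selenoprotein P, changed by -0.49 ± 0.26 (adjusted p = 0.000706). Further falls were -0.46 ± 0.32 for Mprip, which binds myosin phosphatase and RhoA, -0.45 ± 0.27 for the TRAF3-interacting gene Traf3ip3, and -0.43 ± 0.23 for Zcchc7, an RNA surveillance factor. The highly expressed transcripts among them were Srsf5, a splicing factor (-0.32 ± 0.22), Lsp1, an actin-binding protein of lymphocytes (-0.30 ± 0.14), and Hmgb2, a chromatin protein (-0.24 ± 0.16, at 2430 CPM in WT). Sepp1 was the only one of these 9 still called without pair 2, and it was not called without pair 1 (adjusted p = 0.0702).

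**Figure D2:**
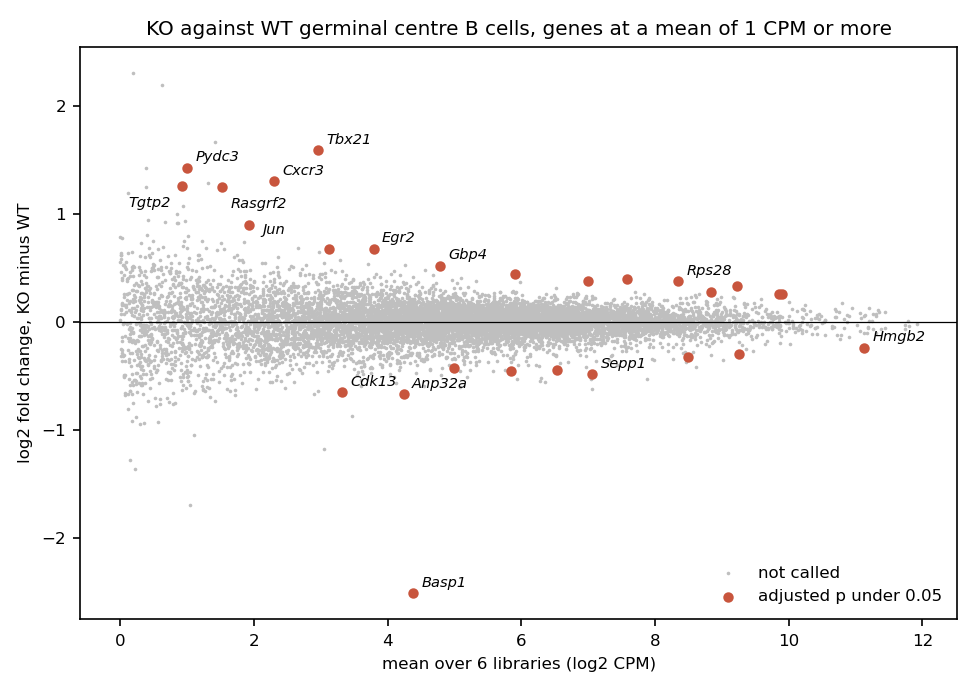
Log2 fold change, KO minus WT, of each of the 10133 tested genes (vertical axis) against its mean over the 6 libraries in log2 CPM (horizontal axis). Red points are the 27 genes past 5% FDR and grey points the rest; Basp1 lies at -2.51 and Tbx21 at 1.59, and the spread of the grey points narrows toward higher levels.

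The genes that define and regulate the germinal centre B cell state were looked at through a set of textbook genes. None of those given here passed 5% FDR. Bcl6, the master repressor of the state, differed by -0.10 ± 0.15 (limma adjusted p = 0.782). Fas differed by -0.20 ± 0.02, lower in all 3 pairs (adjusted p = 0.324), Bach2 by -0.16 ± 0.21 and Foxo1 by -0.27 ± 0.33. The zone markers Cxcr4, Cd83 and Cd86 differed by -0.02 ± 0.03, 0.05 ± 0.36 and 0.02 ± 0.11, and Myc by 0.08 ± 0.07. Mki67, a marker of cycling cells, differed by -0.53 ± 0.48 (adjusted p = 0.763), and passed with non-robust moderation (adjusted p = 0.0427). Irf4 passed with no filter on low values (adjusted p = 0.0398) and without pair 3 (0.0349), Foxo1 without pair 1 (-0.41, adjusted p = 0.00376), and Fas without the replicate block (adjusted p = 0.0352). The plasma cell regulators Irf4 (0.54 ± 0.26, adjusted p = 0.0636) and Prdm1 (0.93 ± 0.56, adjusted p = 0.256, at 1.16 CPM in WT) were higher in all 3 pairs without passing over all genes. Cd38 differed by 0.44 ± 0.35 (adjusted p = 0.168). Of the proteins related to BASP1 in the membrane, Marcks differed by -0.13 ± 0.38 (adjusted p = 0.908), and Gap43 lay at the floor of -5.063 in all 6 libraries.

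Of 32 gene lists fixed before the data were examined, 24 had at least 5 tested members, and 11 of these passed 5% FDR in limma's camera test with a preset correlation of 0.01 between genes, 5 toward KO and 6 toward WT. With a correlation estimated from the data 0 lists passed and 1 had an unadjusted p under 0.05. That variant has only 2 degrees of freedom. The dark zone list, with an estimated correlation of -0.0132, went from an unadjusted camera p of 0.0130 to 0.111. Not passing this variant therefore does not tell that a shift of a list is absent. Passing with the preset 0.01 does not tell that one is present either. Among the lists that passed, only the dark zone list had an estimated correlation below 0.01. The estimate was 0.0192 for the actin list, but 0.254 for germinal centre identity, 0.423 for DNA replication, 0.458 for the light zone and 0.543 for oxidative phosphorylation. If members are correlated that strongly, the preset gives p-values that are too small. By fry, 0 lists passed in its directional test and 2 had an unadjusted p under 0.05. Fry's mixed test, for change in either direction, called 4 lists: cytosolic ribosomal proteins, immediate early genes and the integrated stress response (adjusted p = 0.0371 each), and nuclear and non-coding RNA (adjusted p = 0.000305). The strongest list was that of cytosolic ribosomal proteins. All 57 tested members had a positive fold change, with a median of 0.13, and the medians in the 3 pairs were 0.137, 0.114 and 0.149 (camera adjusted p = 3.9e-23; adjusted p = 0.553 with an estimated correlation; fry p = 0.00256, adjusted p = 0.0614). Of these members 2 (Rps28 and Rps29) rose over all genes, and 22 rose adjusted over the list alone, among them Rpl38 (0.26 ± 0.02) and Rpl37 (0.23 ± 0.12). The fixed list does not hold Rpl41, Rpl37a and Rps26, which also rose over all genes. Transcript length was related to the paired differences, with a Spearman correlation across genes of -0.22 in pair 1, -0.062 in pair 2 and 0.211 in pair 3, and genes are not independent replicates.

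The list of germinal centre B cell identity passed toward WT, with the preset correlation only. Of 20 members 17 had a negative fold change, with a median of -0.10 (camera adjusted p = 4.1e-05; adjusted p = 0.553 with an estimated correlation). Basp1 itself is a member and was the only one that fell over all genes; adjusted over the list alone Basp1 and Nuggc (-0.23 ± 0.11) fell. Without Basp1, 16 of 19 members were negative and the list still passed with the preset correlation (median -0.099, adjusted p = 0.00321; adjusted p = 0.772 with an estimated correlation), while its mean moved from -0.21 to -0.08. With Basp1 in, the medians in the 3 pairs were -0.148, -0.147 and 0.0365, so pair 3 went the other way. The median was -0.076 without pair 1, -0.070 without pair 2 and -0.16 without pair 3. Gcsam, a signalling adaptor of germinal centre cells, differed by -0.16 ± 0.13. The dark zone list, of the cells that divide and mutate, passed with 15 of 23 members negative and a median of -0.038 (adjusted p = 0.0307; adjusted p = 0.553 with an estimated correlation). No member fell, over all genes or adjusted over the list alone, and the call was lost without pair 1 (median -0.031, adjusted p = 0.0538) and without pair 2 (median -0.042, adjusted p = 0.117).

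The light zone list, of the cells under selection by antigen and T cell help, passed toward KO with the preset correlation only. Of 28 members 25 had a positive fold change, with a median of 0.071 (camera adjusted p = 0.000893; adjusted p = 0.772 with an estimated correlation). Egr2 rose over all genes, and Egr2 and Irf4 rose adjusted over the list alone. Bhlhe40 (0.47 ± 0.62) and Relb (0.22 ± 0.17) were among the other members. Targets of NF-kB and CD40 passed with 21 of 36 members positive and a median of 0.074 (adjusted p = 0.0307; adjusted p = 0.772 with an estimated correlation). None rose over all genes, and Irf1 (0.40 ± 0.13) and Irf4 rose adjusted over the list alone. Pair 2 decided both calls: without it the median was 0.0048 for the light zone list (adjusted p = 0.817) and -0.011 for the NF-kB and CD40 list (adjusted p = 0.846). In the same pair the list of nuclear and non-coding RNA, a sign of RNA quality, had a median of -0.505 (-0.106 in pair 1 and 0.261 in pair 3), and the 2 tested erythroid and platelet markers one of 1.98 (0.253 and 0.349). Also in pair 2 the naive and follicular B cell list had a median of 0.298 and the memory B cell list one of 0.504, against -0.116 and -0.198 in pair 1 and -0.063 and -0.017 in pair 3.

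Both lists of the cell cycle passed toward WT, with the preset correlation only. Of 40 DNA replication genes 29 had a negative fold change, with a median of -0.060 (camera adjusted p = 0.00271; adjusted p = 0.772 with an estimated correlation), and the examples were Clspn (-0.32 ± 0.36), Pola1 (-0.20 ± 0.11) and Mcm10 (-0.17 ± 0.23). Of 40 mitosis genes 27 were negative, with a median of -0.042 (adjusted p = 0.00225; adjusted p = 0.553 with an estimated correlation). Cenpf differed by -0.33 ± 0.39 and Kif4 by -0.22 ± 0.22. No member of either list fell over all genes, and adjusted over the list alone 1 mitosis gene did, Casc5 (now Knl1, a kinetochore scaffold; -0.31 ± 0.16). The medians of the replication list in the 3 pairs were 0.003, -0.158 and 0.019, so that only pair 2, the pair with the lowest nuclear RNA median and the highest erythroid one, was lower, and without it the median was 0.003 (adjusted p = 0.846). The mitosis list had pair medians of -0.072, -0.073 and 0.005 and did not pass without pair 2 (median -0.030, adjusted p = 0.0830).

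Both lists of energy metabolism passed toward KO, with the preset correlation only. Of 28 glycolysis and hypoxia genes 25 were positive, with a median of 0.091 (camera adjusted p = 0.000349; adjusted p = 0.553 with an estimated correlation). Ndrg1, which hypoxia induces, differed by 0.73 ± 0.11, beside P4ha1 (0.43 ± 0.44) and the aldolase Aldoc (0.28 ± 0.10). Of 50 oxidative phosphorylation genes 40 were positive, with a median of 0.061 (adjusted p = 0.000319; adjusted p = 0.772 with an estimated correlation), for example Cox7c (0.22 ± 0.08) and Cox8a (0.17 ± 0.05). The oxidative phosphorylation call was lost without pair 1 (median 0.016, adjusted p = 0.304), and the glycolysis median was 0.059 without pair 2 (adjusted p = 0.0187). No member of either list changed, over all genes or adjusted over the list alone.

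The list of actin, calmodulin and MARCKS-family genes, the setting in which BASP1 is known at the membrane, passed toward WT with the preset correlation only. Of 40 members 30 were negative, with a median of -0.053 (camera adjusted p = 0.000349; adjusted p = 0.553 with an estimated correlation). Basp1 was the only member that fell over all genes, and Arpc1b, a subunit of the actin-nucleating Arp2/3 complex, joined it adjusted over the list alone (-0.21 ± 0.18). Without Basp1 the adjusted p was 0.00624, and 0.602 as an adjusted p with an estimated correlation. With Basp1 in, the median was -0.016 without pair 1, and the list still passed (adjusted p = 0.00486). The B cell receptor signalling list passed with 28 of 39 members negative and a median of -0.075 (adjusted p = 0.0199; adjusted p = 0.772 with an estimated correlation). None changed over all genes. Adjusted over the list alone only Cd72, an inhibitory co-receptor, rose (0.32 ± 0.17), against the direction of the list, while Cd79b differed by -0.14 ± 0.06 and Syk by -0.17 ± 0.24. That call was lost without pair 1 (adjusted p = 0.366) and without pair 2 (adjusted p = 0.291).

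**Figure D3:**
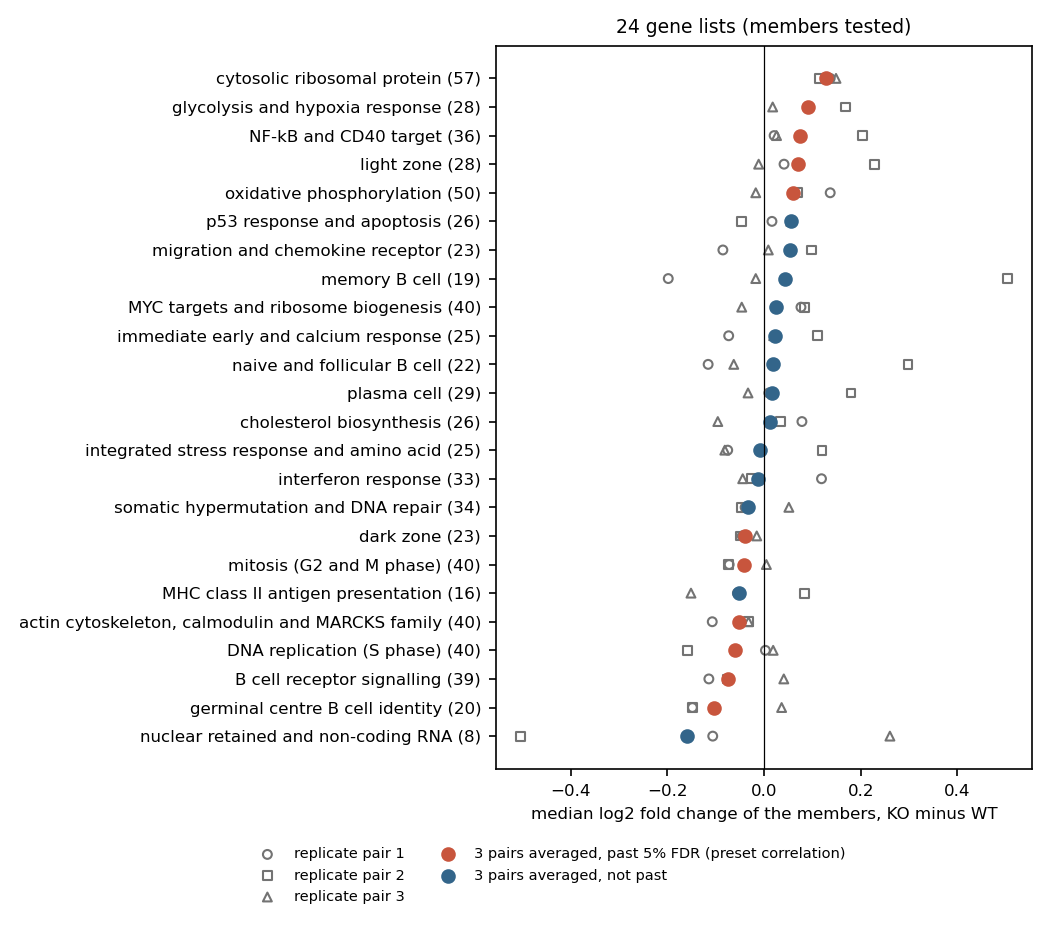
Median log2 fold change, KO minus WT, of the tested members of each of 24 gene lists (horizontal axis), with the number of members in brackets. Filled points average the 3 pairs and are red where the list passed 5% FDR with a preset correlation and blue where it did not; open symbols give the medians of the single pairs, which lie within 0.114 to 0.149 for ribosomal proteins and spread from -0.198 to 0.504 for memory B cell genes.

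The other 13 lists did not pass with all 3 pairs, though several did with 1 pair left out. Without pair 1 the memory B cell list (median 0.21, camera adjusted p = 0.000593) and the naive and follicular list (0.079, adjusted p = 0.0281) passed. Without pair 2 MHC class II presentation (-0.11, adjusted p = 0.00412) and the integrated stress response (-0.070, adjusted p = 0.00281) passed. Without pair 3 the lists of plasma cells (0.079, adjusted p = 0.000995), memory B cells (0.12, adjusted p = 0.0374), MYC targets (0.076, adjusted p = 0.0107), interferon (0.041, adjusted p = 0.0248), hypermutation and DNA repair (-0.064, adjusted p = 0.00983) and nuclear and non-coding RNA (-0.31, adjusted p = 0.00983) passed. Directions also turned: the memory B cell median was -0.13 without pair 2, and that of MHC class II 0.012 without pair 3. With no filter on low values plasma cells and MHC class II passed (adjusted p = 0.0419 each), and with a mean of at least 2 CPM MHC class II did (adjusted p = 0.0492). With all 3 pairs, those of B cell fate were memory B cells (median 0.044, camera adjusted p = 0.0549; Tbx21 rose, and Cd38 also rose adjusted over the list alone), plasma cells (0.017, adjusted p = 0.0828) and naive and follicular B cells (0.018, adjusted p = 0.401; Cd38 rose adjusted over the list alone). In the plasma cell list no member changed over all genes, while Irf4 and Prdm1 rose and Eaf2 (-0.27 ± 0.21) fell adjusted over the list alone. MHC class II presentation had a median of -0.052 (adjusted p = 0.0520), although Cd74 and H2-Ab1 had the same value in all 6 libraries and could not be compared. The interferon list (adjusted p = 0.243) had a median of -0.012, a mean of 0.016 and an upward test direction. Gbp4 and Ifi47 rose, and adjusted over the list alone 6 members rose, among them Irf1, Irgm1 and Oasl2, and Rtp4 fell (-0.93 ± 0.72). In the list of immediate early genes (median 0.022, adjusted p = 0.401) Egr2 and Jun rose, while Jund differed by -0.18 ± 0.11 and Fos by -0.44 ± 0.08 without passing. The lists of p53 response (0.057, adjusted p = 0.119), hypermutation and DNA repair (-0.034, adjusted p = 0.153), MYC targets (0.025, adjusted p = 0.302), the integrated stress response (-0.0083, adjusted p = 0.317), migration (0.054, adjusted p = 0.328) and cholesterol synthesis (0.013, adjusted p = 0.765) completed the tests of cell state. Among their members only Dhcr7, of cholesterol synthesis, passed adjusted over the list alone (0.43 ± 0.12), and none over all genes.

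Of the 21 T cell markers listed 3 reached a mean of 1 CPM, Lat and Cd2 among them, and Cd3e lay at the floor of -5.063 in all 6 libraries. The T cell markers summed to 146 CPM in WT and 125 CPM in KO, mostly from Cd2 (-0.26 ± 0.20), which B cells also express. Macrophage markers summed to 661 CPM in WT and 692 in KO, mostly from Apoe, while Lyz2 differed by -0.66 ± 0.92. Neutrophil markers summed to 2.19 and 1.51 CPM, dendritic and NK cell markers to 131 and 122 CPM, mostly from Flt3, and stromal markers to 47.2 and 40.0 CPM. Erythroid and platelet markers summed to 21.8 CPM in WT and 32.7 in KO, with a median difference of 1.98 in pair 2 against 0.253 in pair 1 and 0.349 in pair 3 over the 2 members tested. No marker of these lists passed 5% FDR over all genes. Adjusted over the list alone, Cd2 and Pecam1 (-0.27 ± 0.08) fell and Car2 (0.44 ± 0.51) rose. Pecam1 lay at 39.0 CPM in WT, while the endothelial genes Cdh5 and Kdr lay at 0.0518 and 0.0299 CPM, so its fall need not concern endothelial cells. With no filter on low values, as lists, erythroid and platelet markers passed toward KO (median 0.60, camera adjusted p = 0.00107) and neutrophil markers toward WT (median -0.76, adjusted p = 0.00622), while the lists of T cells, macrophages, dendritic and NK cells and stromal cells did not. The list of nuclear and non-coding RNA, a sign of RNA quality, had pair medians of -0.106, -0.505 and 0.261 (camera adjusted p = 0.401; fry's mixed test adjusted p = 0.000305, the smallest of the 24 lists), Malat1 in it differed by -0.42 ± 0.81, and adjusted over the list alone only Rpph1 rose (1.08 ± 0.26). Immunoglobulin and mitochondrially encoded transcripts were not analysed here.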

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

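The alternatives that added 1 CPM, dropped the variance trend, raised the limit on the mean to 2 CPM, kept genes with equal values (alone or with non-robust moderation), removed the length and GC trend or left Basp1 out of the lists were chosen after seeing the data. Against 27 genes, no filter on low values gave 95 (42 higher, 53 lower, all 27 among them), non-robust moderation 12 (11 shared), non-robust moderation with genes of equal values kept 3, the test of a fold over 1.2 gave 3, at least 1 CPM in 3 libraries 24, a mean of at least 2 CPM 27 (25 shared), 1 CPM added 27 (all shared), genes of equal values kept alone 22 (all shared), no variance trend 0 (640 at an unadjusted p under 0.05) and removal of the length and GC trend with the block 3. The last moved the fold changes little (Egr2 0.68 before and after, Rps28 from 0.38 ± 0.12 to 0.31 ± 0.13), while the median prior degrees of freedom fell from 81.2 to 15.6. Without the replicate block 142 genes were called, 99 higher and 43 lower, of which 11 were shared, and 2361 genes (23.3%) had an unadjusted p under 0.05. That fit also had many false calls in simulated data. Its median prior degrees of freedom were 2.52 in the libraries, unlike the simulated 81.2, so the simulation does not tell which of the 142 were false. The paired structure cannot be checked by correlation here. Leaving out 1 replicate number gave 11 to 136 genes: 136 without 1 (27 higher, 109 lower, 21 shared), 11 without 2 (4 higher, 7 lower, 4 shared) and 99 without 3 (28 higher, 71 lower, 18 shared), each with 1 residual degree of freedom. Tbx21 and Cxcr3 were called in all alternatives except the one without a variance trend. Basp1 kept its direction throughout (-2.66 to -2.26 with 1 number left out) and lost its call only without the variance trend, at the same -2.51 (adjusted p = 0.150, against 0.0128 or less elsewhere). Of the lists, 0 passed with an estimated correlation and 0 by fry's directional test (4 by its mixed test), against 11, and 7 to 17 with 1 number left out (10 without 1, 7 without 2, 17 without 3); the no-block fit gave 9, no filter 15 (erythroid and platelet and neutrophil markers among them) and the other settings 11 or 12. Among named genes, 3 that had not passed changed sign: Cd83 (-0.153 to 0.193 with 1 number left out) and Cd86 (-0.043 to 0.064) without number 2, and Marcks (-0.266 to 0.085) without number 3. Apart from the cases given, the cause was not tested. Scaling by other factors, count-based tests, voom weights and leaving out immunoglobulin genes were not run, since they need counts or genes not used here. Without read depth, small differences in genes below 8 CPM cannot be judged against counting error.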

Other observations

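The tests of T or NK cells behind Tbx21 and Cxcr3 and of the kind of interferon response were chosen only after the result was seen; the others were written before it.

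The interferon list was divided, after its values were seen, by the interferon that mainly induces each member. The 10 tested genes classed as induced mainly by interferon-gamma, among them Gbp4, Ifi47 and Irf1, had a mean log2 fold change of 0.26 ± 0.19 (SD over genes), 8 of them positive, while the 23 classed as induced mainly by type I interferon had a mean of -0.09 ± 0.36, 6 of them positive. The difference was 0.25, 0.50 and 0.31 in the 3 pairs, and a permutation test of the class labels gave p = 0.00538 (100000 permutations, two-sided, across genes, which are not independent replicates). Tbx21 and Cxcr3, which interferon-gamma also induces in B cells, lie outside this list. A hypothesis is that the KO cells may show a stronger response of interferon-gamma type. Gbp4, Ifi47 and Irf1 had prompted the split, and without these 3 the remaining 7 genes gave a difference of 0.27 with a permutation p of 0.0641. The classes of all members were set after their values were seen, so neither p is independent of the data. The rises of Tbx21 and Cxcr3 were also known by then. The hypothesis stays open.

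The joint rise of Tbx21 and Cxcr3 is the pattern a follow-up would start from. T or NK cells in the KO sort could bring both transcripts. They would bring their abundant markers too, and of 29 such markers the one with the largest rise, Lat, rose by 0.754 CPM, and by 2.77 CPM with 2 SD added, below the 3.88 CPM that Tbx21 reached with 2 SD subtracted (9.11 ± 2.62 CPM). Cd2, which B cells express at 136 CPM, differed by -22.5 ± 17.5 CPM, so that its mean plus 2 SD, 12.5 CPM, lay above this bound although its mean was lower in KO. A trend over transcript length and GC content is argued against by its size. Median log2 fold changes by length class lay within -0.080 to 0.067 in each pair, and the Spearman correlation with GC content within -0.0327 to 0.000947. Removal of such a trend could change little, so it adds no further support. It left the smaller of the 2 log2 fold changes at 1.31 and both genes past 5% FDR by limma (adjusted p = 0.000261 for Tbx21 and 0.00620 for Cxcr3). A response of the B cells themselves to loss of BASP1 remains a hypothesis, and a difference between the mice or sorts of the 2 genotypes stays open.

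Ribosomal protein transcripts were all positive, but ribosomal protein transcripts are short and abundant, and such transcripts can shift together for technical reasons. The list median lay at percentile 100 of 10000 lists matched on length, GC content and level (the central 95% of matched lists lay between -0.026 and 0.027), which argues against a general trend of that kind. No single pair decided it: the median nearest 0 with 1 pair left out was 0.125, against an SD of 0.0178 between the pair medians. What stays open is a shift specific to ribosomal protein transcripts, for instance with growth state or with the time from sort to lysis, which the labels do not give. It may be a property of these 3 pairs. With the estimated correlation between members, 0.0781, the unadjusted camera p was 0.0312. That test has only 2 degrees of freedom, so its p cannot decide this.

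Mitosis genes were slightly lower in KO as a list, with a preset correlation only (adjusted p = 0.553 with an estimated one). The list median lay at percentile 1.08 of lists matched on length, GC content and level, which argues against such a trend as the source. Whether 1 pair decided it cannot be told apart from a shared shift: without pair 2 the median was -0.030, within the SD of 0.0447 between the pair medians. A lower share of dividing cells in KO could give the pattern and was not measured.

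With 3 libraries against 3 there are 10 splits into equal groups, too few for a share under 0.05. For genes, 3 of the 10 splits gave as many as the real 27, and the highest other gave 132; for lists, 7 of the 10 gave as many as the real 11, and the highest other gave 16. The 132 genes came from the splits of WT 1, WT 2 and KO 1 and of WT 1, KO 1 and KO 2 against the rest, which each part only pair 2 and so return its difference alone. This count, several times the real one, points to a structure of the samples in which pair 2 stands apart. The splits that part 1 pair repeat each other and hold the difference of KO and WT in that pair. The shares of the 10 splits therefore do not measure chance. Among the 4 splits that part all 3 pairs, the real one gave 27 genes and 11 lists. The others gave 0, 3 and 1 genes and 16, 11 and 6 lists.

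Genes close to a targeted allele can differ between genotypes because they were carried along from the strain in which the allele was made. Of 19 tested genes within 10 Mb of Basp1 other than Basp1 itself, 0 had an unadjusted p under 0.05 by limma (upper 95% limit 17.6%), against 893 of 10113 elsewhere (8.83%; Fisher's exact test, one-sided p = 1). Sepp1 lies on the same chromosome beyond this distance.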
